A study of Mus musculus with 6 samples.

How the data were processed

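Total RNA from oesophageal squamous cell carcinomas of 6 mice, 3 per labelled genotype, was sequenced on an Illumina HiSeq 2500, per the labels and the design text. RNA was extracted with RNAiso Plus, treated with DNase and checked for integrity, per the labels' protocols, and whether the libraries kept strand is not given in the sources used here. The design text gives 3 mice per group, so libraries were taken as separate mice. The labels disagree on age: a tag gives week 6 and the design text 34 weeks, the latter matching treatment from week 6 for 16 weeks and 12 weeks of follow-up. The labelled carcinogen concentration (100 mg/mL) is copied as given.

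The authors aligned reads with Bowtie 0.12.2 to mm10, per the submitters' processing notes. The deposited file of each sample holds whole read counts per Ensembl transcript with the gene symbol and transcript length, and its RPKM column is the count relative to transcript length and to the summed counts of that library. Ribosomal RNA reads had been removed, judging by the names of the deposited files. How reads shared by several isoforms were assigned is not given in the sources used here. For Ptpro nearly all were listed under 1 of the 3 transcripts, so the counts cannot tell its isoforms apart. The authors also deposited a gene table of FPKM values and one of gene counts scaled to a common size, a signal that is not whole and was not treated as raw counts. The tool and scaling behind those tables are not given in the sources used here. The 2 further columns of these tables were not used.

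Counts were summed per gene symbol (41253 symbols from 100249 transcripts), and 0 reads lay on entries without a gene name. Of the transcripts, 97.2% were in GENCODE M21 (GRCm38, the same assembly as mm10), which gave positions. Of the symbols, 183 covered several Ensembl genes, and the gene with most reads then gave the position. The design foresaw limma on log values if the deposited count table did not hold counts. The scaled table did not, but the per-sample files did, so edgeR was used on those, and limma on the scaled table was added as an alternative. Libraries of one label were not duplicates: chi-square per degree of freedom between pairs ran from 66.9 to 307 over genes with at least 20 reads, and the correlation of log2 CPM across genes from 0.968 to 0.993.

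Genes were filtered with filterByExpr (at least 10 counts, scaled by library size, in 3 libraries, and 15 in total), leaving 17663. They were scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, libraries labelled Ptpro-KO minus those labelled WT. The Benjamini-Hochberg threshold was 0.05, and the common biological coefficient of variation was 0.40. CPM values use TMM library sizes, and log2 CPM for list means has a prior count of 2. The standard error of a log2 fold change is its size over the root of the F statistic. With n = 3 per label, adjusted p values given beside means come from edgeR or limma 3.58.1 fits across all genes. At 25745240 to 39827467 reads per library the spread between mice, not counting error, limits all but the rarest transcripts.

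The samples, tests, 46 gene lists (694 members) and rules for naming genes were set before the data were examined. All 46 lists had at least 3 tested members. They were tested with limma camera at a preset correlation of 0.01. With a correlation estimated per list 0 of the 46 passed, the lowest adjusted p being 0.0748. That was the stress keratin list, whose estimated correlation of 0.01 equalled the preset, where its camera adjusted p was 3.5e-12. Failing under the estimated setting therefore does not by itself show correlated genes. The named genes were the R3 receptor phosphatases, and in each direction the 12 called genes with the largest log2 fold change among those with mean log2 CPM of at least 1, separated groups and an informative symbol. To these came up to 4 members per called list with the smallest p in its direction, and up to 3 abundant members of cell-type lists that varied within a label by over 3 log2 units, a limit set after the data were examined. The text gives a part of them, and the result of 1 list member is not reported here. Names outside the rule were chosen after their values were seen. They were Krt7, Tg, Xist, Cdh1, Epcam, Spp1, Kcnq1, Tnfsf11, Ltf, the Ptpro neighbours, and stomach and gland transcripts. List members named for moving against their list or in the closing part were chosen likewise.

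The pipeline was tested on simulated counts made from these libraries' means and dispersions with known changed genes. For the comparison of labels, with 17422 simulated genes tested, it recovered 1 of 100 genes changed 2-fold and 49 of 100 changed 4-fold, and called 7 unchanged genes. A list raised 2-fold was called, as were 0 of 43 others, with genes simulated as independent. Alternatives were DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), other scalings and filters, other thresholds, a block for replicate number, a term for the library name prefix (LB or B), and leaving out each library. A sex term, limma on the scaled table, and leaving out both libraries with almost no skeletal muscle transcripts were added after seeing the data. So was leaving out the skeletal muscle and stomach lists together with Tg. Camera was also run, as planned, on genes found in 1 list only. Genes near Ptpro were compared by Fisher's exact test.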

Results

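RNA sequencing measured gene expression in oesophageal squamous cell carcinomas of C57BL/6 mice. The tumours had been induced with 4NQO, a water-soluble carcinogen that damages DNA, given in the drinking water from 6 weeks of age for 16 weeks. The design compared mice without the receptor-type tyrosine phosphatase gene Ptpro with mice that carry it, with 3 mice per genotype at 34 weeks of age; per the labels, mice with marked weight loss were killed earlier. The 3 libraries labelled WT held 37595506, 25745240 and 29406034 reads on annotated transcripts. Those labelled Ptpro-KO held 35551442, 39827467 and 35845461. The 10 most abundant genes took 13.6% to 17.9% of the reads of a library. Reads from Xist and the Y chromosome showed 1 female and 2 male mice among those labelled WT, and 2 females and 1 male among those labelled Ptpro-KO.

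The gene named in the genotype went against the labels. Ptpro encodes a membrane tyrosine phosphatase, and a mouse without it was to show fewer of its transcripts. It lies on chromosome 6 from position 137252319 to 137463233 of GRCm38 (mm10), plus strand, ENSMUSG00000030223. The libraries labelled WT held 174, 9 and 67 Ptpro reads, and those labelled Ptpro-KO held 1094, 1824 and 1921. In CPM (reads of a gene relative to the scaled library total), the values were 5.05, 0.359 and 2.39 against 30.3, 42.8 and 50.6, with means of 2.60 ± 2.35 and 41.2 ± 10.3 (SD, n = 3 each). Ptpro was thus 15.7-fold higher in the libraries labelled Ptpro-KO (log2 fold change 3.97, SE 0.85), and all 3 lay above all 3 labelled WT. The edgeR quasi-likelihood test gave an adjusted p of 0.0617, which does not pass 0.05. For Ptpro expression the alternatives, DESeq2 among them, ranged from 4.02e-06 to 0.229. An exact two-sided permutation test of log2 CPM gave p = 0.1, the smallest that 3 libraries against 3 allow. The authors' FPKM table gave 0.730 ± 0.655 against 7.36 ± 1.73 (SD, n = 3 each). Which exons the targeted allele lacks is not in the labels, and the reads were not given per exon. Every direction below is therefore stated between libraries as labelled, and Ptpro itself runs against those labels.

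**Figure D1:**
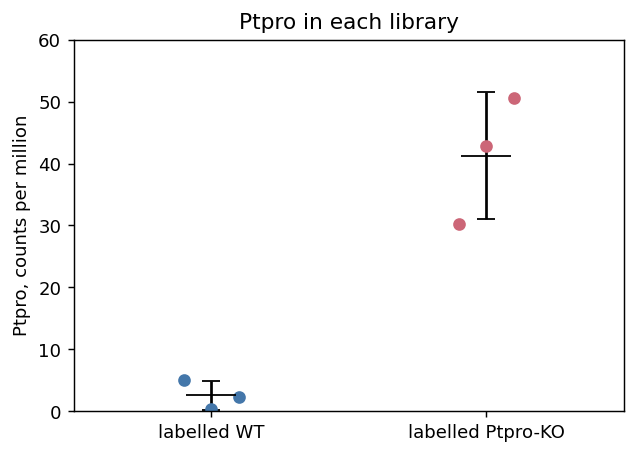
Ptpro expression in CPM (vertical axis) in the 3 libraries labelled WT and the 3 labelled Ptpro-KO; points are libraries, the wide horizontal line is the group mean and the capped bar its SD. The libraries labelled WT lie between 0.359 and 5.05, all below those labelled Ptpro-KO, which lie between 30.3 and 50.6.

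The widest gains in the libraries labelled Ptpro-KO included keratins of simple epithelium. Krt8, a keratin of single-layered epithelia, rose from 0.585 ± 0.173 to 383 ± 246 CPM (SD, n = 3 each), a log2 fold change of 9.34 (SE 0.86, adjusted p = 0.0125 by edgeR). Its partner Krt18 rose from 3.62 ± 1.32 to 216 ± 38.1 CPM, and Krt19 from 0.720 ± 0.886 to 294 ± 96.7 CPM (log2 fold changes 5.90 and 8.62, adjusted p = 0.0125 and 0.0217). Krt8 and Krt18 are neighbours on chromosome 15, at 101996698 to 102004482 and 102028180 to 102032027, and Krt19 lies on chromosome 11 at 100140810 to 100148665. The water channel gene Aqp5, expressed in glands, rose with a log2 fold change of 6.51 (SE 0.92). Others of the 12 genes with the largest gains were the homeobox gene Msx3 (7.13), the choline transporter-like gene Slc44a4 (7.001), Prr15l (6.95) and Mgat3, a glycosyltransferase of N-glycans (6.78). The protease inhibitor A2m (6.38), the lipoxygenase Alox15 (6.26), the coagulation factor F7 (6.08) and the proton pump subunit Atp6v0d2 (6.04) completed them. All 12 had an edgeR adjusted p between 0.0125 and 0.0386. Msx3 rested on 4 reads in the 3 libraries labelled WT together, against 793 in the others.

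The genes with the largest losses included desmosomal cadherins of keratinocytes. The desmosomal cadherin genes Dsg1a and Dsc1, on chromosome 18, fell from 405 ± 145 to 56.3 ± 6.16 CPM and from 595 ± 120 to 99.7 ± 10.04 CPM (SD, n = 3 each). Their log2 fold changes were -2.85 (SE 0.28) and -2.58 (SE 0.19), with edgeR adjusted p of 0.0132 and 0.0125. Csta1, of the cystatin A protease inhibitor family, fell by 2.58 on the log2 scale. Ndufa4l2, which encodes a mitochondrial protein induced by low oxygen, fell by 2.77. Larger log2 losses came from less abundant genes, among them Cryba2 (-3.95), threonine dehydrogenase Tdh (-3.63), the glutamate receptor Grm4 (-3.56) and Slitrk5 (-3.44). Cyp4a10 (-3.29), Glyat (-2.99), Efcab1 (-2.97) and Atp13a4 (-2.70) were the others of the 12. Adjusted p for the 12 ranged from 0.0125 to 0.0492. Csta1 and Dsg1a have close paralogs, as do Krt6a and Krt6b, Hspa1a and Hspa1b and the Lce and Sprr genes named later, and Krt8 and Krt18 have pseudogene copies, so reads may have been divided between copies.

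Across 17663 genes tested, edgeR called 320 higher and 405 lower in the libraries labelled Ptpro-KO at an adjusted p under 0.05. Of these, 266 and 269 differed by at least 2-fold. Each of the 725 had its 3 libraries of one label above the 3 of the other. So did 5742 of all tested genes, 32.5% against 10% by chance. The calls rested on the full set of libraries: without WT replicate 2, WT replicate 3 or Ptpro-KO replicate 2, edgeR called 0 genes, with 3369, 3078 and 4363 at an unadjusted p under 0.05 and 2247, 2030 and 3172 called by DESeq2. Leaving out WT replicate 1 gave 50 higher and 82 lower, Ptpro-KO replicate 1 gave 41 and 52, and Ptpro-KO replicate 3 gave 253 and 243; DESeq2 on all libraries called 1682 and 1478, and a term for the sex of the mouse, chosen after seeing the data, gave 64 and 122.

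Gene lists of squamous epithelium were lower in the libraries labelled Ptpro-KO. Of 16 stress keratins and alarmins, which keratinocytes make on injury, 6 fell and 0 rose over all genes tested, and 12 fell when adjusted over the list alone. Krt6b fell from 21850 ± 1759 to 5764 ± 445 CPM (SD, n = 3 each; log2 fold change -1.92), and the interleukin-36 genes Il1f6 and Il1f9 fell by 2.57 and 2.06 on the log2 scale. The list had a limma camera adjusted p of 3.5e-12, and adjusted p = 0.0748 with an estimated correlation. Of 16 genes of the basal squamous layer, 5 fell over all genes and 7 when adjusted over the list alone. Krt14 fell from 12950 ± 2414 to 4880 ± 778 CPM, Krt5 from 7507 ± 873 to 3240 ± 582, and the desmosomal gene Dsc3 from 877 ± 61.3 to 335 ± 9.77 (SD, n = 3 each). This list had a camera adjusted p of 2.12e-06, and adjusted p = 0.323 with an estimated correlation. In the suprabasal list of the oesophagus, 8 of 18 genes fell, 11 when adjusted over the list alone, where Ecm1, Emp1 and Mal rose. The protease inhibitor Spink5 fell from 1749 ± 441 to 303 ± 34.2 CPM, and Endou, Krtdap and Cnfn fell by 2.22, 1.74 and 1.39 on the log2 scale. Camera gave that list an adjusted p of 1.03e-05, and adjusted p = 0.323 with an estimated correlation. Of 19 epidermis-type cornification genes, 3 fell (Lce3c, Sprr1b and Sprr2h), or 7 adjusted over the list alone. The camera adjusted p was 6.36e-07, and adjusted p = 0.561 with an estimated correlation.

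Stress-response and metabolic lists were also lower. Of 18 targets of NRF2, the regulator of the antioxidant response, Gstm1 and Gclm fell, by 1.45 and 2.02 on the log2 scale, and 9 fell when adjusted over the list alone (camera adjusted p = 2.12e-06; adjusted p = 0.568 with an estimated correlation). Of 10 heat shock genes, 4 fell over all genes and 4 adjusted over the list alone. They were Dnajb1 (-1.06), Hspa1b (-0.92), Hspb1 (-1.36) and Hspa1a (-0.79), and the list had a camera adjusted p of 4.68e-05, and adjusted p = 0.323 with an estimated correlation. Among 15 glycolysis genes all 15 fold changes were negative, but 1 passed the test over all genes and adjusted over the list alone: Pfkp, which fell by 1.08 (camera adjusted p = 1.23e-05; adjusted p = 0.568 with an estimated correlation). All 21 ribosomal protein genes had negative fold changes with a median log2 of -0.37, and 0 passed the edgeR test, over all genes or adjusted over the list alone (camera adjusted p = 0.000138; adjusted p = 0.733 with an estimated correlation). Of 11 genes of the EGFR family and its ligands, 0 fell over all genes and 3 adjusted over the list alone; Ereg had a log2 fold change of -1.27 and Epgn of -3.40 (camera adjusted p = 0.00461; adjusted p = 0.323 with an estimated correlation). The smallest median shifts among these lower lists were in 20 oxidative phosphorylation and 22 proliferation genes, with median log2 fold changes of -0.13 and -0.23. In both, 0 genes passed over all genes or adjusted over the list alone (camera adjusted p = 0.0326 and 0.0354; both adjusted p = 0.767 with an estimated correlation).

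Fibroblast and matrix genes were higher in the libraries labelled Ptpro-KO. Of 20 such genes all had positive fold changes, 4 rose over all genes and 13 adjusted over the list alone. Col1a1, the main fibrillar collagen chain, rose from 82.6 ± 14.1 to 542 ± 153 CPM and its partner Col1a2 from 142 ± 65.9 to 676 ± 179 CPM (SD, n = 3 each). Sparc and Col5a1 rose by log2 fold changes of 1.53 and 2.13. Not all fibroblast genes of the list passed adjusted over it alone. Pdgfra (1.84) and Pdgfrb (1.235) did, while Dcn (0.39), Dpt (0.54), Lum (0.87) and Ogn (1.24) did not. The camera adjusted p was 1.39e-10, and adjusted p = 0.568 with an estimated correlation. Of 16 genes of epithelial-mesenchymal transition and invasion, Sparc and the matrix glycoprotein gene Tnc (log2 fold change 2.42) rose and Snai2 fell; adjusted over the list alone, 5 rose and 1 fell (camera adjusted p = 0.0181; adjusted p = 0.644 with an estimated correlation). Of 14 matrix proteases and inhibitors, 0 rose over all genes and 5 adjusted over the list alone, with Timp1 at a log2 fold change of 3.45 and Ctsk at 2.12 (camera adjusted p = 0.0174; adjusted p = 0.719 with an estimated correlation). Endothelial genes did not pass as a list, with a median log2 fold change of 0.24 and a camera adjusted p of 0.271.

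Some immune lists were higher as well, with few single genes past the test. WT replicate 2 had the lowest list mean in the macrophage, both interferon, MHC class II and B cell lists. Its mean log2 CPM was 2.67 for macrophages, against 4.38 and 3.38 in the other libraries labelled WT. For the interferon response it was 1.59 against 3.48 and 3.06. In the STAT3 list WT replicate 3 was lowest (3.98). T and NK cells (camera adjusted p = 0.322), neutrophils (0.24), mast cells and eosinophils (0.146) and MHC class I presentation (0.0538) did not pass. Of 21 macrophage and dendritic cell genes, 0 passed over all genes, while 13 rose adjusted over the list alone. Fold changes were positive in 16 and negative in 5. Among the negative were the dendritic cell genes Cd207 (-2.15 on the log2 scale), Flt3 (-0.44) and Xcr1 (-0.07). Their means were at most 2.48 CPM under either label, and none passed adjusted over the list alone. Itgax, which dendritic cells also express, rose by 2.06 and passed adjusted over the list alone. It stood at 62.1, 7.98 and 39.4 CPM in the libraries labelled Ptpro-KO, against 9.95, 6.26 and 10.04. Whether dendritic cell genes shared the rise is therefore not settled. The mannose receptor Mrc1 had means of 36.9 ± 35.7 and 306 ± 120 CPM and the Fc receptor Fcgr3 of 10.6 ± 7.91 and 79.5 ± 27.2 CPM (SD, n = 3 each). The camera adjusted p was 8.57e-05, and adjusted p = 0.719 with an estimated correlation. Of 17 interferon-gamma chemokine and guanylate-binding protein genes, Ido1 rose (log2 fold change 4.62), on 6 reads in the libraries labelled WT together, and it rose with Irf1 and Gbp2 adjusted over the list alone (camera adjusted p = 1.88e-05; adjusted p = 0.719 with an estimated correlation). In the wider interferon response list of 22 genes, 0 passed over all genes or adjusted over the list alone (camera adjusted p = 0.0218; adjusted p = 0.767 with an estimated correlation). Of 10 MHC class II presentation genes 0 passed over all genes and 1 adjusted over the list alone (camera adjusted p = 0.00904; adjusted p = 0.733 with an estimated correlation). Of 10 B and plasma cell genes 0 passed either way (camera adjusted p = 0.0024; adjusted p = 0.719 with an estimated correlation). Of 14 STAT3 targets the acute-phase gene Hp (log2 fold change 3.03) and Il4ra (0.77) rose, and 3 rose adjusted over the list alone (camera adjusted p = 0.0355; adjusted p = 0.767 with an estimated correlation).

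Of the 3 R3 receptor phosphatases tested, the family of Ptpro, 0 passed over all genes and Ptpro and Ptprj rose adjusted over the list alone (camera adjusted p = 0.0355; adjusted p = 0.568 with an estimated correlation). Ptprj had a log2 fold change of 0.59 and Ptprb of 0.23. Of 7 tested genes of salivary and mucous glands, Krt8, Krt18 and Aqp5 rose, and adjusted over the list alone 4 rose, Muc5ac being the other, and Lpo fell (camera adjusted p = 0.00128; adjusted p = 0.323 with an estimated correlation). Krt8, Krt18 and Aqp5 are shared with other epithelia, and Muc5ac, a stomach mucin, stood at 5.45, 0.680 and 743 CPM in the libraries labelled Ptpro-KO. Of the untested gland genes, Prol1, Smr2 and Dcpp2 had 0 reads in every library. The gland mucin Muc5b stood at 0.116, 0.159 and 0.214 CPM in the libraries labelled WT and 0.111, 24.8 and 3.43 in those labelled Ptpro-KO. Of 4 tested stomach epithelium genes, 0 passed over all genes and 4 rose adjusted over the list alone (camera adjusted p = 0.048; adjusted p = 0.733 with an estimated correlation). Its largest values came from 1 library, though the call held without it: Tff1 stood at 2797 CPM and Pgc at 6209 CPM in Ptpro-KO replicate 3, but at 9.13 and 3.49 in replicate 1 and 0.610 and 1.38 in replicate 2. In all 3 libraries labelled WT, Pgc had 0 reads and Tff1 at most 0.239 CPM. By limma fry, which tests for a common direction, 5 lists passed: the stress keratin, basal, suprabasal and heat shock lists downward and the gland list upward. The list means of the 3 libraries of one label all lay above those of the other in 17 of the 23 called lists. These lists were called between the same labels in the same libraries, so this separation has no chance rate to be set against. The list means overlapped in 6: cornification, proliferation, B and plasma cells, MHC class II, interferon response and STAT3 targets. Of the 23 camera calls, 15 held whichever library was left out. Camera at this preset correlation also called 13 to 24 lists under other splits of the 6 libraries, so holding is weak evidence for the labels. Without WT replicate 1 the oxidative phosphorylation call was lost, and without WT replicate 2 those of interferon response, proliferation and MHC class II. Without WT replicate 3 the R3, STAT3, invasion and matrix protease calls were lost. Without Ptpro-KO replicate 1 the R3, proliferation, interferon response, invasion and matrix protease calls were lost, and without Ptpro-KO replicate 2 the R3, proliferation, STAT3, interferon response and oxidative phosphorylation calls. The interferon response and R3 calls were also lost with the sex term.

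**Figure D2:**
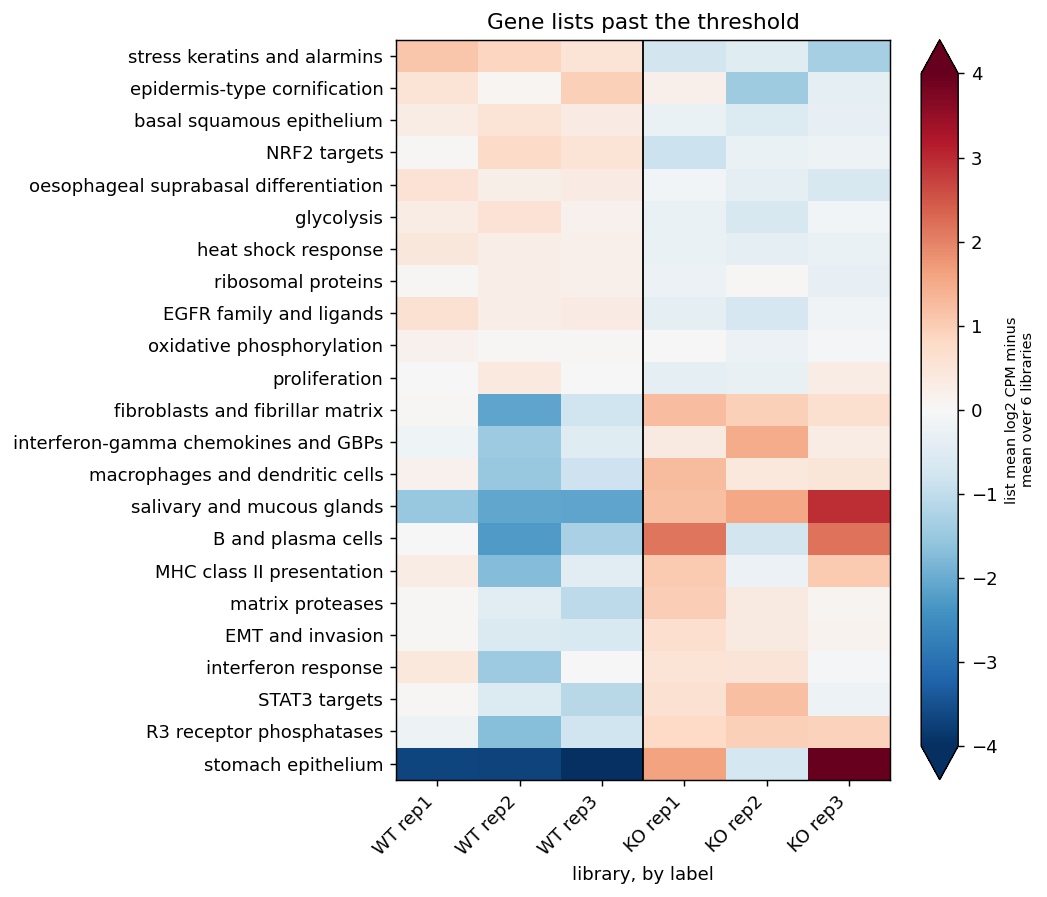
Mean log2 CPM of each of the 23 gene lists past the camera threshold, minus its mean over the 6 libraries (colour), for each library by its label (columns). The 11 lower lists are above and the 12 higher lists below; the fibroblast and matrix list is lowest in WT replicate 2, and the stomach list lies beyond the colour range in Ptpro-KO replicate 3 (high) and WT replicate 3 (low).

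Transcripts of skeletal muscle, stomach and thyroid differed between libraries of one label. Skeletal muscle genes took 4.34%, 0.00855% and 2.92% of reads in the libraries labelled WT and 4.83%, 2.004% and 0.0262% in those labelled Ptpro-KO, so WT replicate 2 and Ptpro-KO replicate 3 stood apart. Stomach genes took 1.99% of reads in Ptpro-KO replicate 3 and at most 0.003% in each other library. The thyroid hormone precursor Tg reached 774 CPM in Ptpro-KO replicate 2, against 0.570 to 2.60 CPM in the others. Beside these, Krt8 stood at 109, 456 and 583 CPM in the 3 libraries labelled Ptpro-KO, so it was high also in replicate 1, where stomach and thyroid transcripts were few. Without WT replicate 2 and Ptpro-KO replicate 3 together, an alternative chosen after seeing the data, edgeR called 0 genes, with 3627 at an unadjusted p under 0.05 and 1967 called by DESeq2. The camera test then gave 14 higher and 13 lower lists, 22 of them among the 23.

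**Figure D3:**
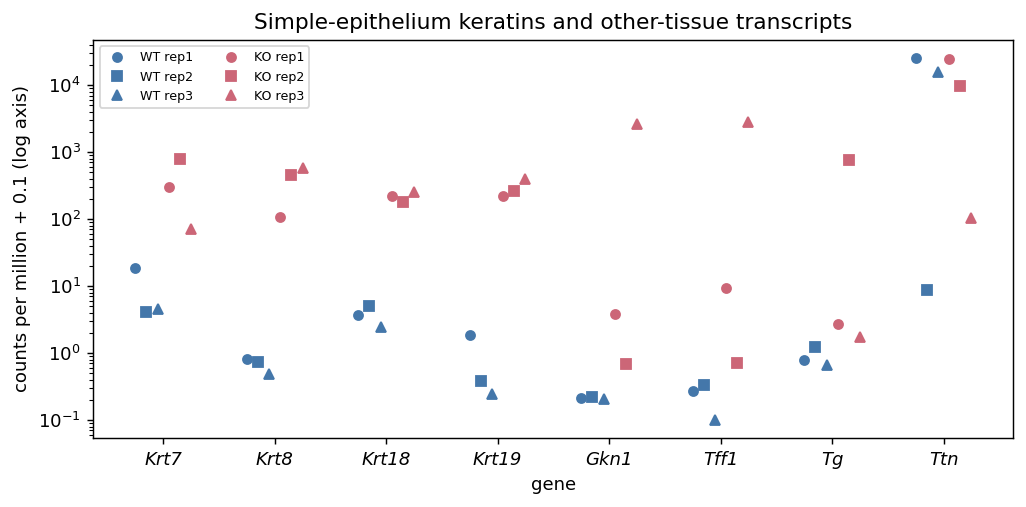
CPM plus 0.1 (vertical log axis) of 4 simple-epithelium keratins, the stomach genes Gkn1 and Tff1, thyroid Tg and the muscle gene Ttn (horizontal axis) in each library; colours give the label and shapes the replicate. Krt8, Krt18 and Krt19 are above the libraries labelled WT in all 3 labelled Ptpro-KO, while Gkn1 (2603) and Tff1 (2797) are high in replicate 3 and Tg (774) in replicate 2.

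Genes that flank Ptpro were compared because a targeted allele can carry neighbouring sequence of another strain. Of 46 tested genes within 5 Mb on either side, Ptpro itself left out, 3 passed the edgeR threshold (Plbd1, Aebp2 and Gprc5a), or 6.52% against 4.12% of the 17494 other genes with a position. The odds ratio was 1.62 (95% interval 0.321 to 5.09), and a two-sided Fisher's exact test gave p = 0.439. An excess near Ptpro was not detectable with so few genes. These 3 were chosen by position, after the calls were made.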

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

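All tests in this part were chosen after the results were seen.

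The authors' 2 gene tables, which the comparisons did not use together, gave a signal about Ptpro isoforms. The scaled count divided by FPKM should follow the transcript length that a gene's fragments were assigned to. For Ptpro it was 118.7, 117.4 and 121.5 in the libraries labelled WT and 185.7, 187.4 and 186.5 in those labelled Ptpro-KO, a ratio of 1.56. Of 15828 genes with FPKM over 0.05 in each library, 3 had a ratio this high, Ptpro included; that FPKM minimum was lowered after a higher one had left Ptpro out. Of 4725 genes with 1 transcript in the files, 4718 had a ratio within 10% of 1. The files list a long form of Ptpro of 6617 bases (chromosome 6, 137252465 to 137463227) and a short form of 4163 bases from an internal start (137410721 to 137463233). The long form is 1.59 times the length of the short one, close to the ratio between the labels in these tables. The per-transcript counts differ from that for the libraries labelled WT: they list 173, 8 and 66 of the 174, 9 and 67 Ptpro reads under the long form and 0 under the short one. Which form those libraries held is therefore open. WT replicate 2 had only 9 Ptpro reads behind its value.

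For higher Ptpro reads in the libraries labelled Ptpro-KO, 3 explanations were weighed. Leukocytes that use the short Ptpro form would not give the 1.56 ratio, in which the added reads came with the longer length. That ratio rests on tables whose making is not given. It also differs from the per-transcript counts for the libraries labelled WT, so this explanation is not decided. Genotype labels exchanged between the groups stay open: the highest library labelled WT reached 16.7% of the lowest labelled Ptpro-KO, but this restates the pattern and any cause of higher Ptpro gives it. A transcript of the targeted allele that is still counted stays open too, because the deleted exons are not known here and the per-transcript counts gave 99.4% of Ptpro reads in these libraries, and nearly all in those labelled WT, to 1 long isoform. These 3 explanations cannot be told apart with the values at hand, and no genotype can be assigned from them.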

How the results depend on the processing

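The sex term and limma on the scaled table were chosen after seeing the data. So were the 2 alternatives that left out muscle-poor libraries or skeletal muscle and stomach genes with Tg. The rest were planned unless stated. Counts of higher and lower genes (320 and 405) rose to 1682 and 1478 with DESeq2 and to 1052 and 958 at an adjusted p under 0.1, and 269 lower genes remained at 2-fold or more. They fell to 133 and 104 with the replicate block, to 64 and 122 with the sex term and to 0 and 0 by edgeR without both muscle-poor libraries (3627 at an unadjusted p under 0.05, DESeq2 1967); the cause was not tested. Of the genes called under the block, 172 were among the 725, and 170 under the sex term. Leaving out 1 library gave 0 to 253 higher and 0 to 243 lower genes, and the libraries named with B alone, also chosen afterwards, gave 0 by edgeR, with 2971 at an unadjusted p under 0.05 and 1934 by DESeq2; those named with LB, 1 of each label, allow no test. Other scalings, filters and limma fits stayed within 1.5 times both counts, as did the term for the library name prefix (392 and 332, of which 515 were among the 725). Higher genes were 44.1% of the calls, and 43.8% and 46.4% with other scalings. They were 54.1% with the prefix term, 56.1% with the block, 53.2% with DESeq2 and 34.4% with the sex term, so lower genes were not the majority in each fit. The 12 higher and 11 lower lists became 0 and 0 with an estimated correlation and 1 and 4 with fry. Leaving out 1 library gave 9 to 16 higher and 10 to 13 lower, and the replicate block ended the interferon response call. Camera on genes found in 1 list only gave 11 higher and 12 lower lists, 21 of them among the main calls. This setting ended the STAT3 target and invasion calls and added the neutrophil and hypoxia lists. The log2 fold change of Ptpro expression was above 0 in each alternative. It passed 0.05 with DESeq2 (3.98), limma-voom (4.53) and limma on FPKM + 1 (2.32), over adjusted p of 4.02e-06 to 0.229, and ranged from 3.46 to 4.89 when 1 library was left out. The filter of 10 reads in every library gave no value for Ptpro. Windows of 2 and 10 Mb gave exact p of 0.532 and 0.649 for genes near Ptpro. Among 2140 values of 109 other named genes, 1636 kept their side of the threshold, 419 no longer passed, 85 newly passed and 0 reversed. Nearly all were named for separated groups or small p in these same libraries, so the absence of reversals is no support. Some, such as Slc2a1 (edgeR adjusted p = 0.103), had not passed in the main fit, so keeping their side includes staying above the threshold. The replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at 0.54, 0.08 and -0.24, and WT replicate 2 correlated best with Ptpro-KO replicate 3 (0.41).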

Other observations

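The tests of explanations and the splits in this part were chosen after the results were seen. The genes in this paragraph were chosen after their values were seen. Osteopontin (Spp1), a secreted matrix protein, stood at 3.64 ± 1.27 CPM in the libraries labelled WT and 156 ± 64.4 in those labelled Ptpro-KO (SD, n = 3 each; log2 fold change 5.42, edgeR adjusted p = 0.0125). The potassium channel gene Kcnq1 stood at 2.72 ± 0.362 and 32.6 ± 9.60 CPM (3.58, adjusted p = 0.0125). The cytokine gene Tnfsf11, which drives osteoclast formation, stood at 0.258 ± 0.0509 and 3.11 ± 0.0948 CPM (3.56, adjusted p = 0.0125). Lactoferrin (Ltf), of the neutrophil list, varied within both labels: it reached 867, 6469 and 164 CPM in the libraries labelled Ptpro-KO, against 119.5, 26.7 and 8.05, and did not pass (adjusted p = 0.126).

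The other 23 lists did not pass camera. Their adjusted p was 0.0538 for hypoxia, MHC class I presentation and MAPK feedback genes, 0.0598 for p53 targets and 0.0603 for the Notch pathway. Immediate early genes (0.0802), cholesterol synthesis (0.081), nerve and glia (0.143), mast cells and eosinophils (0.146) and neutrophils (0.24) did not pass either. T and NK cells had a median log2 fold change of 0.45 and an adjusted p of 0.322, smooth muscle 0.296, adipocytes 0.849, skeletal muscle 0.849 and red blood cells 0.987. The unfolded protein response (0.338), NF-kB and inflammatory cytokines (0.414), Wnt targets (0.582), xenobiotic metabolism (0.80), mitochondrially encoded genes (0.267), thyroid and trachea (0.232), endothelium (0.271) and sex-linked transcripts (0.551) complete them. In the thyroid and trachea list the median (-1.37) and mean (0.72) log2 fold change differed in sign. Among these 23 lists, single genes passed over all genes tested: Ccnd1 (log2 fold change 1.26), Retnlg (3.20), Notum (2.56) and Cyp1b1 (2.61) rose, and Cdkn1a (-0.69), Nrarp (-1.14) and Ugt1a7c (-1.12) fell. When adjusted over the list alone, 4 MAPK feedback genes rose, 2 p53 targets fell, and of the Notch pathway 1 rose and 3 fell. In the same way 1 gene each rose in hypoxia, MHC class I presentation and neutrophils, and 1 adipocyte gene fell. Of NF-kB and inflammatory cytokines 1 rose and 1 fell, of Wnt targets 2 rose and 1 fell, and of xenobiotic metabolism 1 rose and 2 fell.

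Krt7, Krt8, Krt18 and Krt19 were higher in all 3 libraries labelled Ptpro-KO, Krt7 without passing the test (adjusted p = 0.0623). Stomach mucosa in replicates 1 and 2 is argued against: at the ratio seen in replicate 3, stomach transcripts would account for at most 0.245% of these keratins there. Thyroid tissue in replicates 1 and 3 is argued against in the same way, at no more than 0.676%. Stomach mucosa in replicate 3, where the stomach list took 1.99% of reads, stays open for that library. Another glandular tissue, or tumour cells with simple-epithelium keratins, was not tested.

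Squamous lists were lower and matrix and macrophage lists higher in the libraries labelled Ptpro-KO. A lower share of squamous epithelium alone would shift the fibroblast and endothelium lists alike. The fibroblast list moved beyond the endothelium list by 1.68 log2 units (SE 0.55, exact permutation p = 0.1, the smallest possible). The difference was 2.3, 0.64 and 1.67 in the libraries labelled WT and 3.34, 3.61 and 2.7 in those labelled Ptpro-KO. Both list shifts were known when the lists were paired, so this restates them, and a lower squamous share stays open. More females among the libraries labelled Ptpro-KO were weighed as a cause in a model with sex as a term. In that model the mean of 69 squamous genes still differed between labels by -1.13 log2 units (SE 0.17, -1.06 without sex). Adding sex thus did not reduce the squamous shift. These genes came from lists taken because they fell between the same labels, so a remaining shift was partly selected for. Sex as the cause is therefore not excluded. For the 41 matrix and macrophage genes the shift was 1.39 (SE 0.56, 1.66 without sex). With 6 libraries that error is too wide to decide, so sex stays open for these genes. Not every epithelial gene fell. Cdh1 stood at 368, 383 and 369 CPM in the libraries labelled WT and 375, 376 and 481 in those labelled Ptpro-KO. Epcam stood at 46.5, 73.9 and 30.5 against 213, 422 and 203. Chosen after their values were seen, these genes cannot tell squamous from other epithelium. A change in stromal content together with the labelled genotype stays open, and which genotype is which rests on labels that Ptpro itself runs against.

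The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The labelled split called 725 genes by edgeR and the highest other split 1, with DESeq2 at 3160 and at most 200. For lists, the labelled split gave 23 by camera and the highest other 24, so 2 of 10 splits gave as many. The split with 24 parts the libraries by sex, and with a sex term the labels gave 11 higher and 12 lower lists, 21 of them among the 23. The other 8 splits gave 13 to 22 lists. With an estimated correlation camera gave 0 lists in each of the 10 splits.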
